A study of Mus musculus with 31 samples.

How the data were processed

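The values analysed are raw read counts per Ensembl gene, as deposited by the authors in 1 table for 31 libraries of total RNA from mouse liver and kidney, female per the labels. RNA was isolated with an RNeasy kit and libraries were made with TruSeq chemistry, per the labels. Reads were trimmed with Trim Galore 0.6.4 and cutadapt 2.4, checked with FastQC 0.11.8 and placed on GRCm38, per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Each column was matched to its sample by the description in the labels, and 0 columns were left over. All 55536 gene IDs were found in the annotation used here for names and coordinates.

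Groups were genotype by age within tissue: liver at 3, 6 and 18 weeks and kidney at 4, 8 and 18 weeks. Total counts ranged from 10663545 to 19474861 in liver and from 11587221 to 20874412 in kidney, so that 3 counts stood for up to 0.281 CPM in a single liver library. The floor used for a group at 0 was 3 counts over all libraries of the group together, and so lower in CPM. Each tissue was fitted by itself in edgeR 4.0.16 under R 4.3.3 with TMM normalization, filterByExpr by group (minimum count 10), 1 coefficient per group and the quasi-likelihood F test. Groups of 2 or 3 libraries share the estimate of spread of their tissue, and where leaving out a library left a lone sample in an arm, that sample was assumed to vary like the other groups. NIF was compared with 24abNOD at each age, differences between ages were tested as differences of these contrasts, and liver was compared with kidney at 18 weeks in a joint fit over 19463 genes. Calls are Benjamini-Hochberg adjusted p under 0.05. Group values are mean CPM with SD, from TMM-scaled library sizes.

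Where a group held 0 counts, the fold is given as "at least", from a floor of 3 counts over that group. With 1 to 3 counts the ratio is given with its 95 percent counting interval. List medians were also computed with such genes at their bounds.

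Genes were named by a rule fixed before the data were examined. It takes Rag1, Rag2 and the immunoglobulin and T cell receptor segments as a class. It takes the 8 highest and 8 lowest log2 fold changes among called genes with mean log2 CPM of at least 1 and no overlap of the groups, without segments and unnamed gene models. It takes fixed markers (Col1a1, Col3a1, Acta2, Timp1, Cd3e, Cd79a and Adgre1, with Clec4f, Alb and Cyp7a1 in liver and Havcr1, Lcn2 and Slc34a1 in kidney) and up to 4 members of lowest p in each list. For differences it takes the 5 highest and 5 lowest. Some genes of this rule and of the lists are not reported here, and a gene from outside it is said to be so.

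The 39 fixed gene lists hold 731 members, of which 730 have an ID in the table. They cover extracellular matrix, stellate cell and myofibroblast, matrix turnover, T cell, natural killer and cytotoxic, B cell and plasma cell, monocyte and macrophage, dendritic cell and MHC class II, neutrophil, and type 2 response, eosinophil and mast cell genes. They also cover type I interferon response, interferon gamma response, inflammatory cytokine and chemokine, checkpoint and regulatory T cell, lymphoid aggregate, cell cycle, complement, acute phase, NRF2 and oxidative stress, p53 and unfolded protein response, circadian clock, immediate early, erythroid, adipocyte and exocrine pancreas genes. Liver lists are Kupffer cell, hepatocyte identity, xenobiotic cytochrome P450, bile acid synthesis and transport, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation, cholangiocyte and ductular, sinusoidal and vascular endothelium, and fetal and postnatal liver. Kidney lists are proximal tubule, loop, distal and collecting duct, podocyte and glomerulus, and tubular injury. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists and ages within each tissue. The test was repeated with the correlation estimated from the data and with fry.

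Alternatives to each fit were RLE size factors, no filter on low counts, DESeq2 1.42.0, only the groups compared, the replicate number as a block, removal of receptor segments, and leaving out each library in turn. For overlaps they were an adjusted p under 0.01 and DESeq2. These were fixed before the data were examined. A further pair of fits, without the NIF kidney library numbered 2 at 18 weeks and without the NIF liver library numbered 3 at 3 weeks, was added after seeing the data. Reads were not used here, so reads were not realigned and exons of Rag2 were not examined.

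The pipeline was tested on simulated data with the group sizes of each comparison and the spread of each gene estimated over its tissue. Of 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 57 and 91 for liver at 3 weeks, 44 and 92 at 6 weeks, and 27 and 87 at 18 weeks. For kidney it recovered 48 and 96 at 4 weeks, 50 and 93 at 8, and 44 and 87 at 18. It called 4 to 8 unchanged genes per comparison. Camera recovered 10 of 10 changed and called at most 1 of 40 unchanged lists in each, but correlated lists were not simulated.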

Results

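RNA abundance was measured by sequencing total liver RNA and total kidney RNA of NIF mice and of 24abNOD control mice, all female per the labels. As background from outside the labels, NIF mice carry a transgenic T cell receptor on a NOD background without a working Rag2 gene and develop liver inflammation and fibrosis, and 24abNOD mice carry the receptor with Rag2 intact. Liver was sampled at 3, 6 and 18 weeks, with 3, 3 and 2 libraries of each genotype. Kidney was sampled at 4, 8 and 18 weeks, with 3, 2 and 2 NIF libraries and 2, 3 and 3 control libraries, which makes 31 libraries in all. Total counts ranged from 10663545 to 19474861 per liver library and from 11587221 to 20874412 per kidney library. Levels are given in CPM, counts scaled by library size to a common total, and a single count stood for 0.0513 to 0.0938 CPM in liver and 0.0479 to 0.0863 in kidney. Group values are mean CPM ± SD, and fold changes are NIF over 24abNOD on the log2 scale with their standard error (SE). Counting intervals and floors cover counting error only. Calls are edgeR quasi-likelihood tests at a Benjamini-Hochberg adjusted p under 0.05 over 16067 genes in liver and 18653 in kidney. For each gene called higher or lower that is given with group means, all NIF libraries lay on the same side of all control libraries. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these samples, which may be technical.

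The targeted gene came first. Rag2 (chromosome 2, 101624718 to 101632529, GRCm38) encodes a subunit of the recombinase that assembles antigen receptor genes. Its counts were not lower in NIF libraries in any comparison. In liver the NIF and control groups held 18 and 5 Rag2 counts at 3 weeks, 44 and 15 at 6 weeks, and 11 and 7 at 18 weeks. In kidney they held 98 and 19 at 4 weeks, 61 and 48 at 8 weeks, and 94 and 44 at 18 weeks. Only the kidney at 18 weeks gave a call, with Rag2 higher in NIF by 1.59 (SE 0.343, adjusted p = 0.0344, 2.69 ± 0.666 CPM with n = 2 against 0.886 ± 0.204 with n = 3). That call ended without the NIF library numbered 1 (adjusted p = 0.0965) and without the control libraries numbered 1, 2 and 3 (0.0709, 0.119 and 0.133). Reads of a disrupted gene can come from outside its deleted part, so these gene counts check neither genotype nor labels. Rag1 (chromosome 2, 101638282 to 101649501) had too few counts in each group to be tested.

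Transcripts of rearranged immunoglobulin genes were scarce in NIF tissue at the later ages. In liver the summed immunoglobulin segments stood at 7.85 ± 5.51 CPM in NIF against 15.4 ± 2.23 in controls at 3 weeks, 15.6 ± 4.51 against 107.5 ± 54 at 6 weeks, and 5.31 ± 0.692 against 227.9 ± 24.9 at 18 weeks. Of the 8 segments tested in liver, 0, 7 and 7 were lower at these ages. In kidney the sums were 9.67 and 9.64 CPM at 4 weeks, 8.82 ± 1.65 and 108.8 ± 66.2 at 8 weeks, and 9.30 ± 2.19 and 481.6 ± 436 at 18 weeks, and 0, 4 and 10 of 47 tested segments were lower. T cell receptor segments stood at 64.4 ± 28.3 CPM in NIF against 73.5 ± 13 in liver at 3 weeks, where 0 of 10 were called. They went the other way in liver at 6 weeks, where 195.8 ± 35.7 CPM in NIF stood against 38.7 ± 11 and 7 of 10 segments were higher. They were 2.22 times the control sum of 47.2 ± 18.1 in liver at 18 weeks, where 0 of 10 were called. In kidney they stood at 48.3 ± 6.34 against 29.8 ± 2.10 at 4 weeks, 80.6 ± 8.74 against 37.1 ± 3.56 at 8 weeks and 76.5 ± 16 against 65.6 ± 10.3 at 18 weeks, where 0, 3 and 0 of 7 were higher. Reads of one segment may be split between similar segments, so single segments are less certain than these sums.

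**Figure D1:**
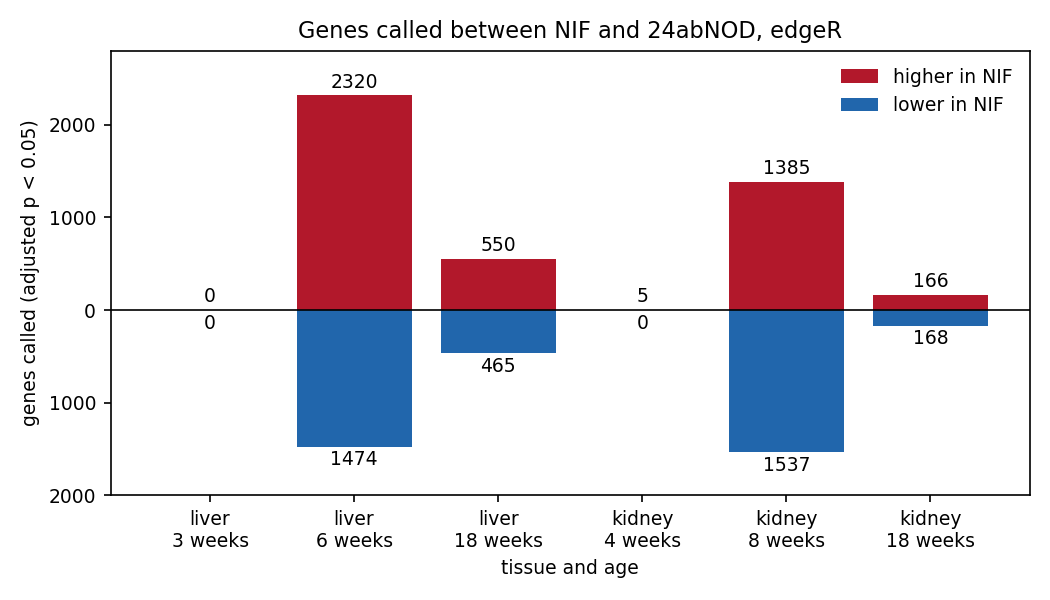
Number of genes called higher and lower in NIF than in 24abNOD at each age in liver and kidney (edgeR, adjusted p under 0.05). Liver at 6 weeks had 2320 genes higher and 1474 lower, and kidney at 8 weeks had 1385 and 1537.

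The comparison at 3 weeks asks which liver transcripts differed at the youngest age sampled. No single gene passed the test. The lists of cholesterol synthesis, fatty acid and triglyceride synthesis and cell cycle genes lay above control with a preset correlation but not with an estimated one (adjusted p = 0.287, 0.31 and 0.389), and the control library numbered 3 lay as high as NIF libraries in them. Srebf2 (chromosome 15, 82147181 to 82205379), the transcription factor of sterol synthesis, had the lowest adjusted p, 0.0668, with a log2 fold change of 0.93 (SE 0.131, from 92.4 to 111.4 CPM in NIF against 51.2 to 60.1 in controls, n = 3 each). Fasn, the fatty acid synthase, stood at 685.7 ± 629 against 126.7 ± 53.4 CPM (2.44, SE 0.515, adjusted p = 0.129), and Mvk at a log2 fold change of 1.65 (adjusted p = 0.129). edgeR called 0 genes, 2450 genes had an unadjusted p under 0.05 where 803 would arise by chance, and DESeq2 called 205, of which 73 were lower.

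In the fixed lists, the cholesterol synthesis list was higher in NIF livers at 3 weeks (median log2 fold change 0.93, camera adjusted p = 3.41e-12), and adjusted p = 0.287 with an estimated correlation. Of its 22 genes, 0 were called over all genes and 6 were higher adjusted over the list alone. The cell cycle list was higher (median 0.55, camera adjusted p = 9.78e-08, adjusted p = 0.389 with an estimated correlation, 3 genes adjusted over the list alone), with Plk1 at 1.53 (adjusted p = 0.162) and Pcna at 0.74 (adjusted p = 0.184). The fatty acid and triglyceride synthesis list was higher (median 0.91, camera adjusted p = 0.000169, adjusted p = 0.31 with an estimated correlation, 3 genes adjusted over the list alone). The B cell and plasma cell list was lower (median -1.04, camera adjusted p = 0.000788, adjusted p = 0.176 with an estimated correlation, 0 genes called over all genes and 1 lower adjusted over the list alone). These 4 list calls held without any single library. In the B cell list the NIF library numbered 2 lay with the controls, with levels over the control mean of -1.37, -0.07 and -1.17 in NIF and 0.04, 0.22 and -0.26 in controls. The control library numbered 3 lay with the NIF libraries in the other 3 lists. Its cell cycle level was 1.41 log2 units over the control mean, against 0.88, 0.81 and 1.23 in NIF. Its cholesterol synthesis level was 1.80 log2 units over the control mean, against -0.90 and -0.90 in the other controls and 1.37, 1.15 and 2.37 in NIF, and without it edgeR called 336 genes higher and 194 lower.

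The neutrophil list (median 3.24, camera adjusted p = 0.00802, adjusted p = 0.612 with an estimated correlation, 10 genes adjusted over the list alone) and the acute phase list (median 0.51, camera adjusted p = 0.0121, adjusted p = 0.605 with an estimated correlation, 8 genes adjusted over the list alone) were higher, and 0 of their genes were called over all genes. Both rested on the NIF library numbered 3, whose level over control was 3.86 in the neutrophil list against -0.67 and 0.52 in the other NIF libraries, and 2.52 against -0.19 and 0.52 in the acute phase list. Saa1, an acute phase protein gene with close paralogs, stood at 432.2 ± 671 against 14.7 ± 5.80 CPM (adjusted p = 0.129). Without that library the neutrophil list had adjusted p = 0.507 with the opposite sign and the acute phase list adjusted p = 0.79, and without the control library numbered 3 these were 0.0559 and 0.181. The xenobiotic cytochrome P450 list was lower (median -0.22, camera adjusted p = 0.0187, adjusted p = 0.403 with an estimated correlation, 0 genes either way), a call that ended without the NIF library numbered 3 (adjusted p = 0.507) or the control library numbered 1 (0.0557). Matrix genes gave no list call (extracellular matrix median 0.14, camera adjusted p = 0.933, adjusted p = 0.98 with an estimated correlation). Col1a1 stood at 23.2 ± 2.97 against 11.02 ± 1.24 CPM (adjusted p = 0.164). In none of the comparisons of either tissue did a list call hold with an estimated correlation.

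At 6 weeks the comparison asks what inflamed NIF liver expresses relative to control liver. Collagen, macrophage, granulocyte, T cell and proliferation genes were higher, and genes of hepatocyte metabolism were lower, with 2320 genes higher and 1474 lower and 1814 and 513 of these changed at least 2-fold. Leaving out any single library left 1798 to 2096 genes higher and 681 to 963 lower. Col1a1 (chromosome 11, 94936224 to 94953042), the main fibrillar collagen chain, rose to 70.0 ± 11.8 from 3.84 ± 1.28 CPM (4.17, SE 0.311, adjusted p = 7.95e-06, n = 3 each). Ccl8 (chromosome 11, 82115185 to 82116799), a chemokine of monocytes and T cells, rose to between 97.2 and 124.5 CPM from between 0.0700 and 0.168 (10.05, SE 0.998, adjusted p = 2.75e-05). Cyp2c69 (chromosome 19, 39842814 to 39886799), a cytochrome of hepatocytes, fell to 14.1 ± 11.7 from 409.3 ± 285 CPM (-4.87, SE 0.674, adjusted p = 0.000204).

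By the naming rule, the 8 highest fold changes at 6 weeks included Ccl8, Chil3 and Retnla. Chil3 (chromosome 3, 106147554 to 106167564) held 11729 counts in NIF and 1 in control livers, a ratio of 8880 with a counting interval of 1590 to 351000. Retnla (chromosome 16, 48842551 to 48844461) rose to 286.3 ± 65.7 from 0.265 ± 0.214 CPM (9.99, SE 1.33, adjusted p = 0.000161). The granule genes Ngp, Ltf, Rnase2a, Mpo and Camp completed the 8 highest, each with 1 or 2 control counts and ratios of 5430 (975 to 215000), 3670 (659 to 145000), 2480 (444 to 97900), 1780 (319 to 70400) and 1380 (381 to 11400). The lowest included the metabolic and secretory genes Cyp2c69, Cyp2a4 (-4.81), Cyp2b13 (-4.51), Cyp4a14 (-4.34), Cyp26b1 (-4.29), Mup2 (-4.25) and Sult3a2 (-4.12). The Cyp2, Cyp4a, Mup and Sult3a families have close paralogs between which reads may be split.

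Of the 25 extracellular matrix genes, 20 were higher and 5 not called at 6 weeks (21 higher adjusted over the list alone, camera adjusted p = 1.56e-13, and adjusted p = 0.176 with an estimated correlation). Postn, secreted in remodelling tissue, rose by 4.09 (adjusted p = 1.27e-05), and Col1a2 by 2.73. In the matrix turnover list 13 of 18 genes were higher (median 1.96, or 1.80 with genes of zero control counts at their bounds, 13 adjusted over the list alone, camera adjusted p = 6.8e-08, and adjusted p = 0.0707 with an estimated correlation). These included Timp1 (5.81, adjusted p = 0.000215), Mmp2 (2.31) and Mmp12 (4.72). The stellate cell and myofibroblast list moved both ways, with 3 genes higher, including Tgfb1, the main profibrotic cytokine (1.70), and Cygb (1.78), and 3 lower, including Hhip (-1.36), both over all genes and adjusted over the list alone (median 0.13, camera adjusted p = 0.849, and adjusted p = 0.945 with an estimated correlation). Acta2, the usual myofibroblast marker, stood at 13.3 ± 3.52 against 9.51 ± 3.59 CPM and was not called (0.48, adjusted p = 0.279).

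All 14 neutrophil genes were higher at 6 weeks, also adjusted over the list alone (median 8.22, camera adjusted p = 9.75e-14, and adjusted p = 0.176 with an estimated correlation). Retnlg rose by 8.21 and the receptor Cxcr2 by 6.43. In the type 2 response, eosinophil and mast cell list 17 of 18 genes were higher and 1 lower, also adjusted over the list alone (median 5.85, or 4.17 at the bounds, camera adjusted p = 1.51e-11, and adjusted p = 0.176 with an estimated correlation). Ccl24, an eosinophil chemokine, rose by 5.87 (adjusted p = 0.00026), and Ccl11 held 327 counts against 2, a ratio of 124 (34.0 to 1030). The monocyte and macrophage list had 18 of 20 genes higher (19 adjusted over the list alone, median 2.37, camera adjusted p = 2.28e-11, and adjusted p = 0.176 with an estimated correlation). Among them were Trem2 (5.29, adjusted p = 0.000117) and Ccr2 (4.04). Adgre1, the pan-macrophage marker, rose by 1.78 (adjusted p = 0.00747), to 36.0 ± 3.84 from 10.5 ± 3.41 CPM. The dendritic cell and MHC class II list had 15 of 18 genes higher (16 higher and 1 lower adjusted over the list alone, median 2.38, camera adjusted p = 1.97e-07, and adjusted p = 0.176 with an estimated correlation). Examples were Flt3 (2.85) and Itgax (3.21). In the inflammatory cytokine and chemokine list 15 of 17 rose (16 adjusted over the list alone, median 2.91, camera adjusted p = 2.33e-10, and adjusted p = 0.176 with an estimated correlation). Ccl6 rose by 5.16 and Ccl7 by 6.12. The Kupffer cell list had 6 of 13 genes higher (9 adjusted over the list alone, median 1.21, camera adjusted p = 0.000796, and adjusted p = 0.429 with an estimated correlation). These included Marco (2.78) and Cd163 (2.22). Clec4f, restricted to Kupffer cells, was called (1.18, adjusted p = 0.033), but its adjusted p was 0.0559 and 0.125 without the NIF libraries numbered 1 and 3, and 0.121, 0.0594 and 0.0706 without the control libraries numbered 1, 2 and 3.

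T cell and cytotoxic lists were higher at 6 weeks and the B cell list was not called. Of 19 T cell genes 15 were higher and 1 lower, also adjusted over the list alone (median 1.93, camera adjusted p = 4.36e-07, and adjusted p = 0.176 with an estimated correlation), with the receptor constant gene Trac at 3.13 (adjusted p = 0.000276) and Cd3e at 1.94 (adjusted p = 0.00808). Of 15 natural killer and cytotoxic genes 10 were higher (12 adjusted over the list alone, median 2.27, camera adjusted p = 6.98e-07, and adjusted p = 0.22 with an estimated correlation). Gzma, a cytotoxic protease, rose by 5.09 (adjusted p = 0.000136), and Eomes, a transcription factor of cytotoxic cells, was at least 49.7-fold higher than 0 control counts. The B cell and plasma cell list had 4 genes higher and 4 lower of 13 (4 and 5 adjusted over the list alone, median -1.06, camera adjusted p = 0.866, and adjusted p = 0.956 with an estimated correlation). Ighm fell by 2.65 on the log2 scale, Tnfrsf13b and Fcrla rose by 3.10 and 3.44, and Cd79a held 3 counts against 14, a ratio of 0.162 (0.0299 to 0.581, adjusted p = 0.0521). The checkpoint and regulatory T cell list had 8 of 14 genes higher and 1 lower (9 and 1 adjusted over the list alone, median 1.94, camera adjusted p = 3.08e-05, and adjusted p = 0.176 with an estimated correlation). Among them were Havcr2 (3.58) and Lag3 (2.30). The lymphoid aggregate list had 5 of 7 higher, also adjusted over the list alone (median 3.08, camera adjusted p = 9.72e-05, and adjusted p = 0.21 with an estimated correlation), with the B cell chemokine Cxcl13 at 64.3 ± 6.98 against 0.874 ± 0.41 CPM (6.22, adjusted p = 0.000305).

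Proliferation and acute phase genes rose at 6 weeks too. The cell cycle list had 20 of 23 genes higher (22 adjusted over the list alone, median 3.53, camera adjusted p = 8.36e-16, and adjusted p = 0.176 with an estimated correlation). Top2a stood at 28.3 ± 0.912 against 0.603 ± 0.227 CPM (5.54, adjusted p = 4.52e-05). The acute phase list had 18 of 22 higher, also adjusted over the list alone (median 1.85, camera adjusted p = 4.32e-11, and adjusted p = 0.176 with an estimated correlation). Examples were Hpx (1.90) and Lcn2 (5.87, adjusted p = 0.000419). The interferon gamma response list had 10 of 20 higher (17 adjusted over the list alone, median 1.18, camera adjusted p = 2.33e-06, and adjusted p = 0.389 with an estimated correlation). These included Gbp2 (2.30) and Irf8 (1.76). The complement list had 10 of 19 higher and 1 lower (11 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 9.15e-05, and adjusted p = 0.31 with an estimated correlation). C6 rose by 3.60 and C8a by 1.88.

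Hepatocyte genes were lower at 6 weeks. The xenobiotic cytochrome P450 list had 19 of 26 genes lower (22 adjusted over the list alone, median -1.10, camera adjusted p = 5.02e-11, and adjusted p = 0.0763 with an estimated correlation), such as Cyp2b9 (-2.71, adjusted p = 5.36e-05). The bile acid synthesis and transport list had 11 of 21 lower (12 adjusted over the list alone, median -0.65, camera adjusted p = 5.09e-06, and adjusted p = 0.0707 with an estimated correlation), led by the uptake transporter Slc10a1 (-1.18, adjusted p = 0.000103). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was not called (0.09, adjusted p = 0.921). The fatty acid oxidation list had 15 of 22 lower (16 adjusted over the list alone, median -0.78, camera adjusted p = 3.61e-08, and adjusted p = 0.31 with an estimated correlation). Ehhadh, of peroxisomal beta oxidation, fell by 1.44 on the log2 scale. The hepatocyte identity list had 12 of 23 lower (13 adjusted over the list alone, median -0.73, camera adjusted p = 4.26e-06, and adjusted p = 0.176 with an estimated correlation), including Hpd (-1.29) and Cps1 (-1.13). Albumin was not called (Alb -0.32, adjusted p = 0.2). Of 144 called genes named by the rule at this age, 127 stayed called without each single library in turn.

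**Figure D2:**
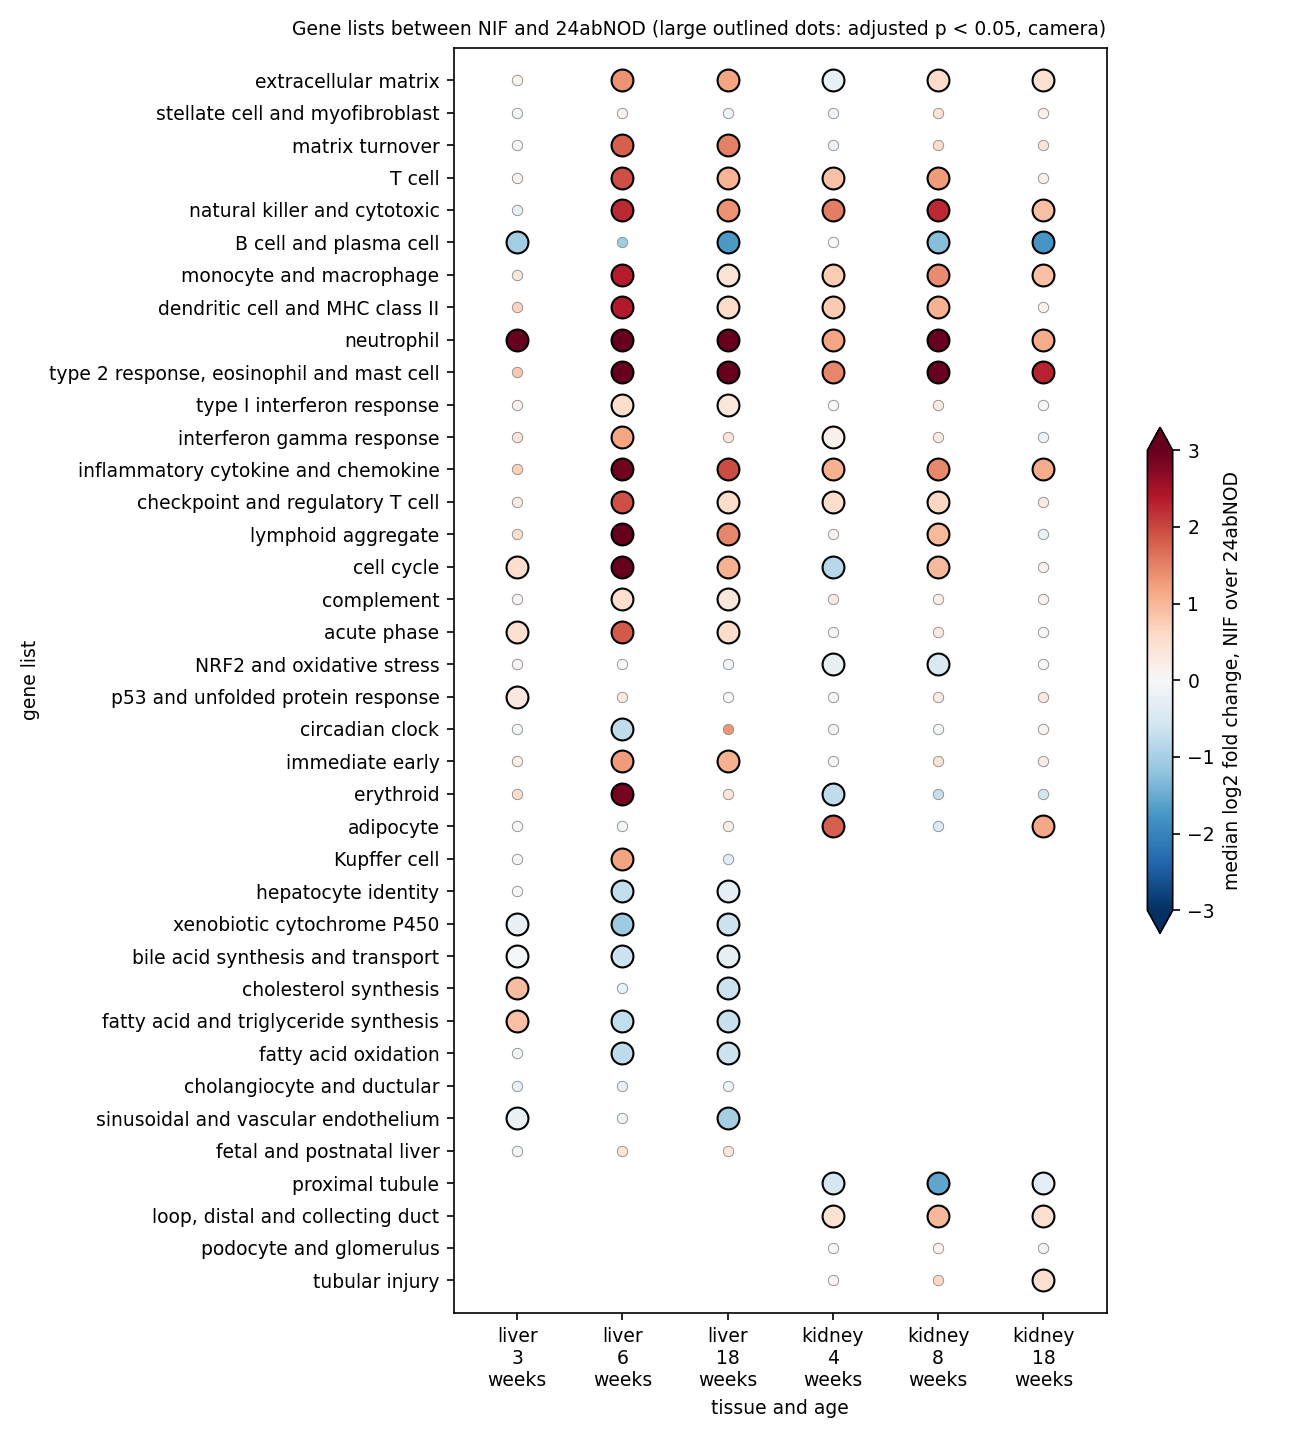
Median log2 fold change of the fixed gene lists, NIF over 24abNOD, at each age in liver and kidney. The neutrophil list stood at 8.22 in liver at 6 weeks and the proximal tubule list at -1.58 in kidney at 8 weeks.

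At 18 weeks the liver comparison asks what persists at the late age. Collagen VI, matrix protease and granulocyte genes were higher and several cytochrome genes were lower, with 550 genes higher and 465 lower (450 and 303 at least 2-fold, n = 2 each). Mitochondrial reads made up 3.83 and 3.45 percent in NIF against 4.26 and 4.47. Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, held 1026 counts against 2, a ratio of 360 (99.5 to 2980, adjusted p = 0.000433). Cib3 (chromosome 8, 72204335 to 72212837), a calcium-binding protein, rose to 159.6 ± 28.2 from 1.35 ± 0.601 CPM (6.85, SE 0.547, adjusted p = 2.53e-05). Cyp2c40 fell to 10.3 ± 2.14 from 383.9 ± 7.66 CPM (-5.22, SE 0.638, adjusted p = 0.000433), and Cyp2c69 was lower as well (-7.58, adjusted p = 0.000597). Ltf was at least 463.7-fold higher than 0 control counts, with adjusted p = 0.0758 and 0.056 without the control libraries numbered 1 and 2. Cyp3a41a, with 0 NIF counts, was at least 984.4-fold lower, with adjusted p = 0.0664 without the NIF library numbered 2. The remaining genes of the rule were Ngp, Camp, Chil3, S100a8 and S100a9 (higher) and Cyp3a16, Serpina4-ps1, Sult3a2, Npas2 and Sult3a1 (lower).

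Matrix genes at 18 weeks included 10 of 25 extracellular matrix genes higher (13 adjusted over the list alone, median 1.19, camera adjusted p = 2.77e-08, and adjusted p = 0.176 with an estimated correlation). Lum (2.71, adjusted p = 0.000309), Col6a1 (2.67), Col6a2 (3.07) and Col6a3 (1.82) rose. Col1a1 stood at 18.1 ± 4.57 against 4.58 ± 2.98 CPM (2.00, SE 0.366, adjusted p = 0.0055), with adjusted p = 0.0592 without the NIF library numbered 2 and 0.0521 without the control library numbered 1. Without the same libraries Col3a1 (1.28, adjusted p = 0.0204) had adjusted p = 0.194 and 0.163. The matrix turnover list had 8 of 18 higher (9 adjusted over the list alone, camera adjusted p = 1.46e-07, and adjusted p = 0.0707 with an estimated correlation). Mmp2 stood at 22.7 ± 4.37 against 1.81 ± 0.0641 CPM (3.64, adjusted p = 2.53e-05) and the macrophage protease Mmp12 at 6.02. The stellate cell and myofibroblast list had 4 genes higher and 1 lower of 16 (5 and 3 adjusted over the list alone), and its median (-0.14) and its test (higher) differed in sign (camera adjusted p = 0.906, and adjusted p = 0.96 with an estimated correlation).

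Immune genes at 18 weeks included 9 of 14 neutrophil genes higher (13 adjusted over the list alone, median 7.18, or 6.43 at the bounds, camera adjusted p = 9.75e-14, and adjusted p = 0.176 with an estimated correlation). In the type 2 response, eosinophil and mast cell list 7 of 18 were higher (10 adjusted over the list alone, median 5.23, or 3.25 at the bounds, camera adjusted p = 3.21e-08, and adjusted p = 0.176 with an estimated correlation). The mast cell proteases Mcpt4 and Cma1 were at least 83.1-fold and 44.7-fold higher than 0 control counts. Of 20 monocyte and macrophage genes 5 were higher, also adjusted over the list alone (median 0.41, camera adjusted p = 1.16e-05, and adjusted p = 0.36 with an estimated correlation), such as Trem2 (4.50, adjusted p = 0.00414), which had adjusted p = 0.0578 without the control library numbered 1. Adgre1 was not called (-0.42, adjusted p = 0.711). The inflammatory cytokine and chemokine list had 6 of 17 higher (10 adjusted over the list alone, median 1.96, camera adjusted p = 2.31e-06, and adjusted p = 0.176 with an estimated correlation). The B cell and plasma cell list had 6 of 13 lower (1 higher and 7 lower adjusted over the list alone, median -1.73, camera adjusted p = 0.0016, and adjusted p = 0.176 with an estimated correlation). Ighm stood at 3.54 and 4.76 CPM against 60.3 and 218.3 (-5.06, adjusted p = 0.00249). The T cell list had 0 of 19 called (1 higher and 1 lower adjusted over the list alone, median 1.02, camera adjusted p = 0.0216, and adjusted p = 0.542 with an estimated correlation), and the natural killer and cytotoxic list 1 of 15, also adjusted over the list alone (median 1.34, camera adjusted p = 0.00828, and adjusted p = 0.503 with an estimated correlation). Without the control library numbered 1 the macrophage, T cell and natural killer lists had adjusted p = 0.363, 0.304 and 0.308, and without the NIF library numbered 2 the T cell list had 0.0917.

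Hepatocyte lists at 18 weeks were lower with fewer called genes. The xenobiotic cytochrome P450 list had 6 of 26 lower and 2 higher (11 and 2 adjusted over the list alone, median -0.64, camera adjusted p = 0.00012, and adjusted p = 0.176 with an estimated correlation). The bile acid synthesis and transport list had 4 of 21 lower (5 adjusted over the list alone, median -0.26, camera adjusted p = 0.0054, and adjusted p = 0.176 with an estimated correlation), among them Cyp27a1 (-1.10, adjusted p = 0.00162). The fatty acid oxidation list had 3 of 22 lower (9 adjusted over the list alone, median -0.64, camera adjusted p = 9.15e-06, and adjusted p = 0.403 with an estimated correlation). The hepatocyte identity list had 2 of 23 lower (3 adjusted over the list alone, median -0.29, camera adjusted p = 0.00509, and adjusted p = 0.389 with an estimated correlation), a call that ended without the NIF library numbered 1 (adjusted p = 0.0783). The sinusoidal and vascular endothelium list had 1 of 18 higher, Cd34 (2.52, adjusted p = 6.1e-05), and 2 lower (1 and 11 adjusted over the list alone, median -1.02, camera adjusted p = 0.000112, and adjusted p = 0.435 with an estimated correlation).

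With 2 libraries per group, single libraries decided many of the calls at 18 weeks. The 1015 calls fell to 340 and 207 without the NIF libraries numbered 1 and 2, and to 314 and 466 without the control libraries numbered 1 and 2, and 23 of 84 called genes named by the rule stayed called in all 4 fits.

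Whether the genotype effect in liver changed with age was tested directly as a difference of differences. Between 3 and 6 weeks it rose for 984 genes and fell for 638 (458 to 1591 and 158 to 731 without single libraries). Of 23 cell cycle genes it rose for 13, and of 23 hepatocyte identity genes it fell for 6. Hmmr, a spindle protein, differed by 6.23 (SE 1.2, adjusted p = 0.00794) and Cyp2c69 by -4.75 (SE 0.852, adjusted p = 0.00595). Lists with upward differences included cell cycle (18 genes adjusted over the list alone, median 2.55, camera adjusted p = 3.66e-08, and adjusted p = 0.312 with an estimated correlation), neutrophil (1 of 14 called, 9 adjusted over the list alone, median 5.39, camera adjusted p = 1.28e-10, and adjusted p = 0.224 with an estimated correlation) and extracellular matrix (14 of 25 called, 17 adjusted over the list alone, median 1.19, camera adjusted p = 6.63e-13, and adjusted p = 0.165 with an estimated correlation). Lists with downward differences included xenobiotic cytochrome P450 (8 of 26 called, 17 lower and 2 higher adjusted over the list alone, median -1.09, camera adjusted p = 2.36e-07, and adjusted p = 0.165 with an estimated correlation) and fatty acid and triglyceride synthesis (6 of 20 called, 10 adjusted over the list alone, median -1.62, camera adjusted p = 1.77e-06, and adjusted p = 0.211 with an estimated correlation). Between 6 and 18 weeks 36 genes rose and 49 fell (1 to 76 and 2 to 289 without single libraries). Cyp2a5, a cytochrome of the central lobule, was lower at 6 weeks (-3.27) and higher at 18 weeks, a difference of 5.44 (SE 0.68, adjusted p = 0.00405), and the scavenger receptor Cd163 fell by 3.75 (SE 0.673, adjusted p = 0.0269). Lower as lists were Kupffer cell (1 of 13 called, 10 adjusted over the list alone, median -1.96, camera adjusted p = 6.42e-07, and adjusted p = 0.24 with an estimated correlation), cell cycle (1 of 23, 2 adjusted over the list alone, median -1.95, camera adjusted p = 6.63e-13, and adjusted p = 0.227 with an estimated correlation) and acute phase (0 of 22, 10 adjusted over the list alone, median -1.06, camera adjusted p = 8.38e-07, and adjusted p = 0.269 with an estimated correlation). Of 10 genes named for the later difference, only Arntl stayed called without each library, and the call of Cyp2a5 at 18 weeks ended without the NIF library numbered 2 or either control library.

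At 4 weeks the kidney comparison asks whether NIF differed from control outside the liver at the youngest kidney age. It called 5 genes higher and 0 lower (NIF n = 3, control n = 2), 1676 genes at an unadjusted p under 0.05, and 47 higher and 33 lower by DESeq2. Mitochondrial reads made up 8.02, 8.66 and 11.1 percent in NIF against 6.11 and 5.71 in controls, and ribosomal RNA 0.233, 0.196 and 0.205 against 0.177 and 0.149. Retnla rose to 57.6 ± 17.3 from 0.313 ± 0.0157 CPM (7.49, SE 0.979, adjusted p = 0.0192), and the monocyte chemokine Ccl8 to 29.4 ± 6.13 from 0.160 ± 0.141 CPM (7.48, SE 1.1, adjusted p = 0.0395). Col6a5 (chromosome 9, 105856078 to 105960643), a collagen VI chain, rose by 4.51 (SE 0.606, adjusted p = 0.0192) and the protease inhibitor Serpina3g by 3.37 (SE 0.453, adjusted p = 0.0192). The remaining called gene, Cd84, a receptor of immune cells, lay outside the naming rule and was chosen after its values were seen (3.10, SE 0.408, adjusted p = 0.0192). No gene was called without the NIF library numbered 1 or without either control library, and 6 and 7 were called higher without the NIF libraries numbered 3 and 2.

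Among the lists at 4 weeks, the type 2 response, eosinophil and mast cell list was higher (1 of 13 called, 7 adjusted over the list alone, median 1.46, camera adjusted p = 1.95e-11, and adjusted p = 0.136 with an estimated correlation). The monocyte and macrophage list (0 of 20 called, 10 adjusted over the list alone, median 0.75, camera adjusted p = 5.57e-09, and adjusted p = 0.219 with an estimated correlation) and the natural killer and cytotoxic list (0 of 11, 3 adjusted over the list alone, median 1.53, camera adjusted p = 6.02e-08, and adjusted p = 0.136 with an estimated correlation) were higher too, with Lyz2 at 1.61 (adjusted p = 0.19) and Gzma at 79 counts against 1, a ratio of 64.5 (11.3 to 2580, adjusted p = 0.0511). The T cell list was higher (0 of 20 called, 3 higher and 1 lower adjusted over the list alone, median 0.89, camera adjusted p = 4.31e-06, and adjusted p = 0.219 with an estimated correlation). The cell cycle list was lower (0 of 23 called, 5 lower adjusted over the list alone, median -0.84, camera adjusted p = 3.04e-12, and adjusted p = 0.211 with an estimated correlation). Cdc20 stood at -1.40 (adjusted p = 0.318). The extracellular matrix list was lower (0 of 25 called, 3 lower adjusted over the list alone, median -0.26, camera adjusted p = 5.71e-05, and adjusted p = 0.564 with an estimated correlation), a call that ended without the NIF library numbered 3 (adjusted p = 0.25). Col1a1 stood at 51.2 ± 20.3 against 100.7 ± 9.13 CPM (-0.98, adjusted p = 0.356). The erythroid list was lower (0 of 8 called, 3 adjusted over the list alone, median -0.77, camera adjusted p = 0.0198, and adjusted p = 0.285 with an estimated correlation), a call that ended without the NIF library numbered 3 (0.0949).

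The proximal tubule list was lower (0 of 20 called, 3 lower adjusted over the list alone, median -0.52, camera adjusted p = 4.31e-06, and adjusted p = 0.375 with an estimated correlation) and the loop, distal and collecting duct list higher (0 of 17 called either way, median 0.46, camera adjusted p = 4.46e-06, and adjusted p = 0.375 with an estimated correlation) at 4 weeks. Slc13a3, a proximal dicarboxylate transporter, stood at 265.2 ± 48.1 against 612 ± 54.6 CPM (-1.21, adjusted p = 0.19).

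At 8 weeks the comparison had the most calls of the kidney ages, with 1385 genes higher and 1537 lower (754 and 761 at least 2-fold, NIF n = 2, control n = 3). Mitochondrial reads made up 7.82 and 8.39 percent in NIF against 6.50 to 7.23 in controls. Macrophage, cytotoxic and type 2 genes and genes of the distal nephron were higher, and proximal tubule genes were lower. Retnla rose to 280.3 ± 76.7 from 1.48 ± 0.716 CPM (7.59, SE 0.719, adjusted p = 0.000152) and Ccl8 by 7.81 (SE 0.772, adjusted p = 0.000162). Cyp4a10 (chromosome 4, 115518264 to 115533649), a fatty acid hydroxylase of the proximal tubule, fell to 74.2 ± 1.68 from 912.2 ± 324 CPM (-3.62, SE 0.283, adjusted p = 0.000132). Umod (chromosome 7, 119462711 to 119479282), uromodulin of the thick ascending limb, rose to 7729 ± 208 from 2784 ± 205 CPM (1.47, SE 0.187, adjusted p = 0.000642). Other genes of the rule included Ccl9, Serpina3g, Csf2rb2, Pappa2, Ccl6 and Cd163 (higher) and Jchain, Tmprss6, Bhmt, Hsd17b2, Cyp4a14 and Bhmt-ps1 (lower). Hsd17b2 and Cyp4a14 lost their calls whichever library of the comparison was left out (highest adjusted p = 0.24 and 0.207), and Tmprss6 and Bhmt lost theirs without either NIF library (highest 0.0871 and 0.0588).

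Immune lists at 8 weeks included all 8 neutrophil genes higher, also adjusted over the list alone (median 4.23, camera adjusted p = 2.06e-08, and adjusted p = 0.136 with an estimated correlation). Csf3r rose by 3.02 (adjusted p = 0.000645), and S100a9 stood at 9.96 ± 8.36 against 0.467 ± 0.251 CPM (4.37). The monocyte and macrophage list had 13 of 20 higher (14 adjusted over the list alone, median 1.42, camera adjusted p = 9.1e-10, and adjusted p = 0.213 with an estimated correlation). Examples were C1qa (2.68), C1qb (2.59), C1qc (2.81) and Trem2 (3.45), and Adgre1 rose by 1.89 (adjusted p = 0.00244). The type 2 response, eosinophil and mast cell list had 9 of 13 higher (10 adjusted over the list alone, median 3.05, camera adjusted p = 2.73e-09, and adjusted p = 0.136 with an estimated correlation), such as the interleukin 33 receptor Il1rl1 (3.05) and Mrc1 (2.84). The natural killer and cytotoxic list had 8 of 11 higher (10 adjusted over the list alone, median 2.27, camera adjusted p = 1.33e-06, and adjusted p = 0.159 with an estimated correlation). Klre1, a receptor of such cells, rose by 3.61. The T cell list had 8 of 20 higher (13 adjusted over the list alone, median 1.28, camera adjusted p = 1.33e-06, and adjusted p = 0.211 with an estimated correlation), including Trbc2 (1.38, adjusted p = 0.00102). Cd3e was called (1.40, adjusted p = 0.0335), but lost the call whichever library of the comparison was left out (highest adjusted p = 0.251). The dendritic cell and MHC class II list had 9 of 18 higher (12 adjusted over the list alone, median 1.07, camera adjusted p = 5.13e-05, and adjusted p = 0.356 with an estimated correlation). The B cell and plasma cell list had 3 of 17 lower (4 adjusted over the list alone, median -1.28, camera adjusted p = 0.013, and adjusted p = 0.506 with an estimated correlation). Its call ended without the control library numbered 2 (adjusted p = 0.118), whereas Igkc, with 0 NIF counts, was at least 259.5-fold lower.

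Nephron genes moved apart at 8 weeks. The proximal tubule list had 11 of 20 lower (16 adjusted over the list alone, median -1.58, camera adjusted p = 1.59e-10, and adjusted p = 0.222 with an estimated correlation), with the endocytic receptors Lrp2 (-1.85, adjusted p = 0.00168) and Cubn (-1.91) and the transporters Slc13a3 (-2.28, adjusted p = 0.00057) and Slc22a8 (-1.81). The loop, distal and collecting duct list had 15 of 17 higher (16 adjusted over the list alone, median 1.00, camera adjusted p = 1.59e-10, and adjusted p = 0.219 with an estimated correlation). Among them were Slc12a1 (1.29) and Calb1 (1.35). The NRF2 and oxidative stress list had 8 of 17 lower (9 adjusted over the list alone, median -0.49, camera adjusted p = 0.000111, and adjusted p = 0.126 with an estimated correlation), such as Gsta1 (-2.13). The tubular injury list had 4 of 20 higher and 2 lower (6 and 3 adjusted over the list alone, median 0.61, camera adjusted p = 0.199, and adjusted p = 0.702 with an estimated correlation). Lcn2, released by stressed tubules, rose by 2.54 (adjusted p = 0.00483, or 0.0504 without the NIF library numbered 2), and Havcr1, the kidney injury molecule, was not called (-0.57, adjusted p = 0.472). The extracellular matrix list had 5 of 25 higher (8 adjusted over the list alone, median 0.57, camera adjusted p = 4.79e-05, and adjusted p = 0.564 with an estimated correlation). Col1a1 stood at 50.2 ± 16.1 against 26.8 ± 3.75 CPM (0.91, adjusted p = 0.0409), a call that ended whichever library of the comparison was left out (highest adjusted p = 0.404). The counts of genes higher and lower fell to 219 and 253 or 241 and 241 without the NIF library numbered 1 or 2, and to 763 and 980, 721 and 976, and 708 and 963 without the control libraries numbered 1, 2 and 3. Of the called genes named by the rule, 44 stayed called in all 5 fits and 57 did not.

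**Figure D3:**
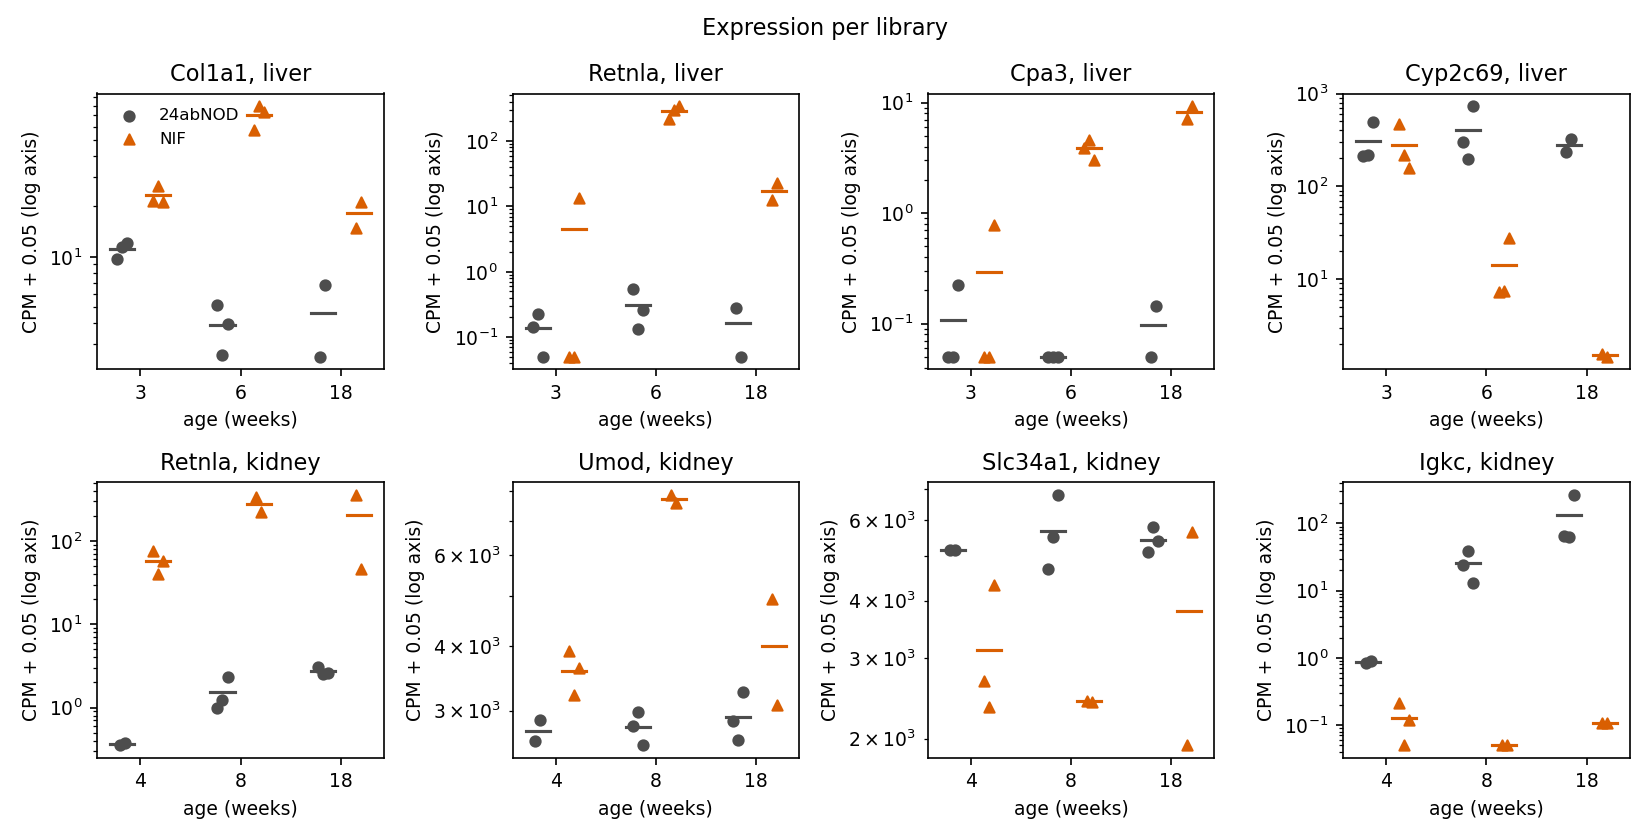
CPM + 0.05 per library on a log axis for Col1a1, Retnla, Cpa3 and Cyp2c69 in liver and Retnla, Umod, Slc34a1 and Igkc in kidney, by age and genotype, with lines at group means. Umod in kidney at 8 weeks averaged 7729 CPM in NIF and 2784 in 24abNOD.

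At 18 weeks the kidney comparison asks which of these differences were present at the late age. Genes of the type 2 response list were higher and immunoglobulin segments lower, with 166 genes higher and 168 lower (124 and 124 at least 2-fold, NIF n = 2, control n = 3). The NIF library numbered 2 held Y chromosome reads and almost no Xist although its label says female, so part of this difference rests on it. Retnla stood at 203.6 ± 224 against 2.66 ± 0.286 CPM (6.25, SE 0.668, adjusted p = 0.00115), Ccl8 at 6.09 (SE 0.671, adjusted p = 0.00118) and Col6a6 at 5.57 (SE 0.846, adjusted p = 0.00607). Gsta1 (chromosome 9, 78230656 to 78242684), a glutathione transferase, fell to 0.257 ± 0.123 from 6.15 ± 1.10 CPM (-4.54, SE 0.425, adjusted p = 0.000767), Jchain by 6.02 and Hpd by 2.11 on the log2 scale. Igkc held 2 counts against 7205, a ratio of 0.000395 (4.79e-05 to 0.00143, adjusted p = 0.00131). The genes Cyp2j13 (8.53, adjusted p = 0.013), Cyp7b1 (4.73, adjusted p = 0.00883) and Slc7a13 (8.20, adjusted p = 0.0184) were high in the NIF library numbered 2. Without it, Cyp7b1 stood at 1.53 (adjusted p = 0.0129), Cyp2j13 at 1.29 (adjusted p = 0.227) and Slc7a13, whose groups overlapped, at 0.13 (adjusted p = 0.937). Wfdc17, Ccl9 and Eddm3b (higher) and Naaladl1, Bhmt, Wfdc16, Abcb1b and Cpn1 (lower) completed the rule, of which Wfdc16 alone stayed called without each single library.

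Of the lists at 18 weeks, the type 2 response, eosinophil and mast cell list had 8 of 13 genes higher (11 adjusted over the list alone, median 2.31, camera adjusted p = 6.95e-12, and adjusted p = 0.136 with an estimated correlation). Il1rl1 stood at 3.94 ± 0.594 against 0.876 ± 0.0495 CPM, and Mrc1 and the mast cell protease Cpa3 rose by 2.31 and 2.86. The B cell and plasma cell list had 5 of 17 lower (9 adjusted over the list alone, median -1.76, camera adjusted p = 1.06e-08, and adjusted p = 0.178 with an estimated correlation). The monocyte and macrophage list had 4 of 20 higher (11 adjusted over the list alone, median 0.91, camera adjusted p = 5.37e-07, and adjusted p = 0.285 with an estimated correlation), a call that ended without the NIF library numbered 1 (adjusted p = 0.0912). Adgre1 was called (1.38, adjusted p = 0.0403), but not without that library (0.296) or the control libraries numbered 1, 2 and 3 (0.156, 0.106 and 0.0953). The inflammatory cytokine and chemokine list had 4 of 14 higher (8 adjusted over the list alone, median 1.11, camera adjusted p = 5.34e-06, and adjusted p = 0.211 with an estimated correlation), and the natural killer and cytotoxic list 2 of 11 (4 adjusted over the list alone, median 0.90, camera adjusted p = 0.000276, and adjusted p = 0.222 with an estimated correlation). Gzma rose by 3.67. The proximal tubule list had 1 of 20 higher and 2 lower (3 and 8 adjusted over the list alone), a median of -0.31 and a mean of 0.17, opposite in sign, and a test downward (camera adjusted p = 5.41e-05, and adjusted p = 0.474 with an estimated correlation). The loop, distal and collecting duct list was higher (0 of 17 called, 6 adjusted over the list alone, median 0.50, camera adjusted p = 4.33e-05, and adjusted p = 0.444 with an estimated correlation). Without the NIF library numbered 1 both nephron lists lost their calls with the opposite sign (adjusted p = 0.0823 and 0.827). Slc22a8 fell by 1.67 on the log2 scale (adjusted p = 0.00407) and stayed called without each single library, but not in a fit of only the groups compared (adjusted p = 0.13).

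A fit of only the groups compared called 0 genes higher and 0 lower at 18 weeks, so each call at this age depends on the spread shared with the other ages. Single libraries moved the counts at this age in both directions. Without the NIF library numbered 2, which held the Y chromosome reads, 1544 genes were higher and 1265 lower, sharing 138 and 152 with the calls of all libraries. Without the NIF library numbered 1 these were 676 and 358, and without the control libraries numbered 1, 2 and 3 they were 44 and 49, 42 and 58, and 57 and 67.

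The genotype effect in kidney differed between 8 and 4 weeks for 1 gene, Cyp4a10, by -2.81 (SE 0.358, adjusted p = 0.0428), with 2620 genes at an unadjusted p under 0.05, and 319 called by DESeq2, of which 194 were lower. That call ended without the NIF library numbered 3 or either control library at 4 weeks, and without either NIF library or the control library numbered 2 at 8 weeks. Between 18 and 8 weeks edgeR called 0 genes, with 2817 at an unadjusted p under 0.05, and 179 higher and 39 lower by DESeq2. Both counts depended on single libraries, as without the NIF library numbered 1 at 18 weeks 1713 genes were called higher and 933 lower, and without that numbered 1 at 4 weeks the earlier difference had 352 and 249. Among lists, 0 genes were called over all genes in any of the differences that follow. The cell cycle (16 adjusted over the list alone, median 1.92, camera adjusted p = 2.49e-13, and adjusted p = 0.446 with an estimated correlation) and extracellular matrix differences (11 adjusted over the list alone, median 0.85, camera adjusted p = 1.77e-10, and adjusted p = 0.466 with an estimated correlation) were positive between 4 and 8 weeks, and fry called neither (adjusted p = 0.0787 and 0.215). The proximal tubule difference was negative between 4 and 8 weeks (4 adjusted over the list alone, median -0.97, camera adjusted p = 1.4e-05, and adjusted p = 0.466 with an estimated correlation) and positive between 8 and 18 weeks (11 adjusted over the list alone, median 1.16, camera adjusted p = 7.28e-05, and adjusted p = 0.466 with an estimated correlation). At 18 weeks its level over control was -1.33 in the NIF library numbered 1 and 0.70 in that numbered 2, which held the Y chromosome reads, so these lay on opposite sides of control. The neutrophil difference was negative between 8 and 18 weeks (6 adjusted over the list alone, median -3.11, camera adjusted p = 2.63e-07, and adjusted p = 0.446 with an estimated correlation).

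Liver and kidney could be compared at 18 weeks, the age sampled in both. The genotype effect was greater in liver for 320 genes and lower for 189. Leaving out single libraries gave from 166 genes in all to 821, the latter without the NIF kidney library with Y chromosome reads. Cyp2c69 (-7.20, SE 1.08, adjusted p = 0.000449) was lower in NIF liver alone, and Dbp, a clock output gene, differed by 5.51 (SE 1.51, adjusted p = 0.0485). Nrg1, a growth factor gene, differed by 9.45 (SE 1.2, adjusted p = 0.000112), a fitted value that depends on the prior count since a liver group held 0 counts. Without the NIF kidney library with Y chromosome reads the negative differences of Slco1a1 and Acsm3 were no longer called (-0.99, adjusted p = 0.527, and 0.36, adjusted p = 0.83), and that of Cyp7b1 shrank from -5.61 to -2.35 (adjusted p = 0.000989).

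The same genes recurred across ages and tissues more often than independent lists would give. In liver 378 genes were higher at both 6 and 18 weeks (79.4 expected) and 237 lower (42.7). In kidney 92 were higher at both 8 and 18 weeks (12.3 expected) and the number lower was 9.25 times the 13.8 expected. Liver at 6 weeks and kidney at 8 weeks shared 540 genes higher (152 expected) and 403 lower (3.32 times those expected). The tissues at 18 weeks shared 33 (4.60) and 32 (3.53). Called in the same direction at 6 and 18 weeks in liver and 8 and 18 in kidney were 30 genes higher and 22 lower. The examples were chosen after seeing their values, some from outside the naming rule. The higher genes included Col6a5 (5.14, 4.20, 5.21 and 5.53 in that order), the macrophage lectin Mgl2 (3.68, 4.34, 2.76 and 2.06), Trem2, Ccl8, Retnla and the mast cell genes Cpa3, Mcpt1, Mcpt2, Mcpt4, Tpsb2, Tpsab1 and Cma1. The lower genes included the peroxisomal enzymes Gstk1 (-0.86, -0.60, -0.82 and -0.54) and Hao2 (-1.74, -1.16, -2.33 and -1.25), the retinol saturase Retsat, and Igkc, Igha and Jchain. No gene was called in all 6 comparisons, given the 0 calls at 3 weeks in liver.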

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

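The tests of genes called at the later ages of both tissues, of the library with Y chromosome reads, of clock genes and of nephron segments were chosen after the result was seen. The number of genes whose genotype effect differed between groups was flagged for 4 of 5 differences tested, all but kidney at 18 against 8 weeks, where it was 0. It was 984 higher and 638 lower for liver at 6 against 3 weeks, 36 and 49 at 18 against 6 weeks, 0 and 1 for kidney at 8 against 4 weeks, and 320 and 189 for liver against kidney at 18 weeks. For liver at 6 against 3 weeks the largest differences on the log2 scale included Hmmr 6.23, Ccnb1 6.00, H19 5.86, Tpx2 5.49 and Nuf2 5.42 upward, and Hamp2 -6.98, Sult3a2 -5.165, Cyp2c69 -4.75 and Mfsd2a -4.505 downward. Of the 10 genes of largest difference, 7 stayed called without each single library. For liver at 18 against 6 weeks they were Cyp2a4 5.98, Cyp2a5 5.44, Per3 4.43, Cib3 3.81 and Cyp2a22 3.69 upward, and Npas2 -4.93, Arntl -4.175, Cd163 -3.75, Srms -3.09 and Tfec -2.965 downward. For kidney at 8 against 4 weeks the gene was Cyp4a10, -2.81. For liver against kidney they were Nrg1 9.45, Folr1 6.74, AI854703 6.33, Scara5 6.12 and Dbp 5.51 upward, and Slco1a1 -7.77, Cyp2c69 -7.20, Irx2 -6.44, Acsm3 -6.08 and Cyp7b1 -5.61 downward. Nrg1, Folr1, AI854703 and Irx2 had 0 counts in a group and Scara5 had 1, so the sizes of these differences depend on the prior count.

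Splits of the same libraries into other groups gave a check against chance. For liver at 3 weeks the real split called 0 genes and the highest other 130. All 10 splits had to reach 0, so this check says nothing. For liver at 6 weeks the real split called 3794 and the highest other 0, so 1 of 10 splits reached it, too few splits for a share under 0.05. For the difference between 6 and 3 weeks the real split called 1622, the highest other called 2893, and 7 of 100 drawn splits reached the real number, so chance was not excluded by this test. The 6 others that did so all kept the libraries at 6 weeks split by genotype, as 10 of the drawn splits did, and the highest of the remaining splits called 8. No gene, 0, was called in all 6 comparisons, so there was no share near Rag2 to test. Of the 52 genes called in the same direction at the later ages of both tissues, 0 lay within 20 Mb of Rag2, where 0.774 were expected (Fisher's exact p = 1), which counts against a chromosome segment around Rag2 as their source.

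The NIF kidney library numbered 2 at 18 weeks was flagged by a signal at odds with its label, with 199.1 CPM on the Y chromosome where no other library exceeded 11.5. Its Xist level was 0.0652 percent of the mean of the other kidney libraries of that age, which goes against a female library with male RNA mixed in. Its Igkc level was 0.0827 percent of the lowest control library, which goes against an exchanged control. All 7 genes of a male-biased kidney list were higher in it than in each other kidney library of that age. Of these, Slco1a1, Acsm3, Cyp7b1 and Slc7a13 had been seen beforehand. All 3 female-biased genes were lower, but were also called lower in NIF kidney at 8 weeks (median -2.53). Their level does not single out a male animal. A male animal likely explains these values, and the differences in Slco1a1 and Acsm3 may then reflect sex and not genotype. That of Cyp7b1 was -2.345 without this library, so only part of it may.

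Clock genes in liver at 18 weeks moved in opposite directions by limb, with Arntl at -4.40 and Per3 at 4.02. The limb medians were -3.24 and 2.01, which lie 5.25 apart, against a gap of -0.694 at 6 weeks and of 0.183 in kidney at 18 weeks. At 6 weeks both limbs were lower (-0.386 and -1.08). The gap, 13.2 percent of the size at 18, misses this, so inflammation as a cause stays open. The clock index differed by 5.66 between the genotypes at 18 weeks, and the widest range within a liver group was 42.9 percent of that. The time of collection is not in the labels, so a difference in time of day and a genotype effect cannot be told apart.

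Nephron segment genes in kidney at 8 weeks could reflect which piece of kidney was taken. The distal convoluted tubule list, a cortical segment, had a median of 0.96 with 6 of 7 genes higher, against 0.865 for inner medulla. Calb1 and Slc12a3 were in the loop, distal and collecting duct list (median 1.00), so this was partly known. It weighs little against more medulla in NIF. The glomerular median, 0.137, lay well below 1.00, which goes against a lower share of proximal tubule cells alone. Neither was shown to explain these medians, and a mixture was not tested.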

How the results depend on the processing

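The alternatives were fixed before the data were examined, except a pair of fits, described below, that were tests chosen after the result was seen. Of the fits of named genes without a single library, 4479 kept their side of the threshold and direction, 594 lost a call, 151 gained one and 1 reversed. Of the list fits, 867 kept it, 44 lost a call, 42 gained one and 11 reversed. A result not called in either fit counts as kept even where its sign differed. RLE size factors changed 3 named gene results, all to a call, and 0 list results. Where a fit leaves out libraries, the smaller number of samples is part of the change, and for all other changes the cause was not tested. Counts that moved by over 1.5 times follow, as higher and lower, and values printed with an exponent are rounded to 2 digits.

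DESeq2 gave 1.3e+02 and 73 for liver at 3 weeks, 47 and 33 for kidney at 4 weeks, 434 and 401 for kidney at 18 weeks, 1492 higher for liver at 6 against 3 weeks, 169 and 342 for liver at 18 against 6 weeks, 1.3e+02 and 194 for kidney at 8 against 4 weeks, 179 and 39 for kidney at 18 against 8 weeks, and 508 and 354 for liver against kidney. Its overlaps were 176 and 281 for kidney at 8 and 18 weeks, and 58 and 58 for both tissues at 18 weeks. With an adjusted p under 0.01 the overlaps were 1.2e+02 and 61 in liver, 23 and 24 in kidney, 168 and 110 for liver at 6 and kidney at 8 weeks, and 8 and 3 for both tissues at 18 weeks. RLE size factors gave 9 genes higher for kidney at 4 weeks, and leaving out the receptor segments gave 8.

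Without a filter on low counts the numbers were 583 and 236 for liver at 3 weeks, 1137 and 753 at 18 weeks, 1557 and 1074 at 6 against 3 weeks, and 324 and 688 at 18 against 6 weeks. For kidney they were 90 and 1.3e+02 at 4 weeks, 635 and 661 at 18 weeks, 306 and 411 at 8 against 4 weeks, and 554 and 130 at 18 against 8 weeks, and for liver against kidney 728 and 488. With only the groups compared they were 251 and 387 for liver at 18 against 6 weeks, 9 and 4 for kidney at 4 weeks, 2391 and 2532 at 8 weeks, 0 and 0 at 18 weeks, 54 and 204 at 8 against 4 weeks, and 158 and 54 for liver against kidney.

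With the replicate block the numbers were 6 and 1 for liver at 3 weeks, 356 and 293 at 18 weeks, 345 lower at 6 against 3 weeks, and 9 and 10 at 18 against 6 weeks. For kidney they were 2 higher at 4 weeks, 306 and 547 at 8 weeks, 16 and 38 at 18 weeks, and 0 lower at 8 against 4 weeks, and for liver against kidney 152 and 76. None of 14 same-numbered pairs had a correlation over 0.1 (from -0.255 to 0.0923), so no sign of pairing by number was seen. In arms of 2 libraries the deviations from the group mean mirror each other, so pairing was not excluded.

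A pair of fits was added after seeing the data. Without the NIF kidney library numbered 2 at 18 weeks in the shared fit, the numbers were 92 and 1.1e+02 for kidney at 4 weeks, 2088 and 2369 at 8 weeks, and 166 and 404 at 8 against 4 weeks. Without the NIF liver library numbered 3 at 3 weeks they were 866 higher for liver at 18 weeks, and 1.1e+02 and 231 at 18 against 6 weeks.

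Of the called lists (10, 25 and 24 in liver and 16, 15 and 11 in kidney, by age), 0, 0, 0, 0, 0 and 0 were called with an estimated correlation. Of all lists tested, fry called 4, 24 and 10 in liver and 5, 12 and 5 in kidney, by age.

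Leaving out each library in turn gave ranges of 0 to 336 higher and 0 to 194 lower for liver at 3 weeks, 1798 to 2096 and 681 to 963 at 6 weeks, 140 to 281 and 58 to 185 at 18 weeks, 458 to 1591 and 158 to 731 at 6 against 3 weeks, and 1 to 76 and 2 to 289 at 18 against 6 weeks. For kidney they were 0 to 7 and 0 to 3 at 4 weeks, 219 to 763 and 241 to 980 at 8 weeks, 42 to 1544 and 49 to 1265 at 18 weeks, 0 to 352 and 0 to 249 at 8 against 4 weeks, and 0 to 1713 and 0 to 933 at 18 against 8 weeks. For liver against kidney they were 1.2e+02 to 574 and 50 to 348. Called lists ranged from 8 to 12, 24 to 26 and 15 to 25 in liver and from 14 to 17, 14 to 19 and 6 to 16 in kidney.

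Signs reversed in these fits, with the range over all left-out libraries in brackets. Without the NIF liver library numbered 3 at 3 weeks, adjusted p was 0.0428 for the macrophage list (0.0428 to 0.97), 0.507 for neutrophil (7.69e-08 to 0.507), 0.014 for interferon gamma response (0.000165 to 0.694), 0.0312 for complement (0.0312 to 0.826) and 0.792 for endothelium (9.91e-05 to 0.792). The Kupffer cell list at 18 weeks had 0.0184 without the control library numbered 2 (2.39e-08 to 0.445). In kidney at 18 weeks without the NIF library numbered 1, adjusted p was 0.36 for extracellular matrix (2.78e-07 to 0.36), 0.0823 for proximal tubule (1.59e-13 to 0.0823), 0.827 for loop, distal and collecting duct (4.08e-11 to 0.827), and 0.187 for tubular injury (1.67e-05 to 0.187). Without that numbered 2 it was 0.0223 for podocyte and glomerulus (6.48e-10 to 0.145). The difference of Acsm3 between liver and kidney was 0.3561 without the NIF kidney library numbered 2 (-7.071 to 0.3561).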

Other observations

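The lists here were fixed before the data were examined, and no test was chosen for this part after the result was seen. The type I interferon response list had 6 of 21 genes higher in liver at 6 weeks (8 adjusted over the list alone, median 0.52, camera adjusted p = 0.00105, and adjusted p = 0.503 with an estimated correlation), with Oas3 at 2.48, and 2 higher at 18 weeks (median 0.36, camera adjusted p = 0.00802, and adjusted p = 0.605 with an estimated correlation), a call that ended without the control library numbered 1 (adjusted p = 0.0881). In kidney at 8 weeks 1 of 21 was higher (median 0.24, camera adjusted p = 0.116, and adjusted p = 0.729 with an estimated correlation). The immediate early list had 3 of 12 genes higher in liver at 6 weeks (4 adjusted over the list alone, median 1.27, camera adjusted p = 0.0131, and adjusted p = 0.491 with an estimated correlation), including Egr2 (4.85) and Ier3 (3.13), a call that ended without the control library numbered 3 (adjusted p = 0.14). The p53 and unfolded protein response list had 5 of 20 genes higher there (5 higher and 1 lower adjusted over the list alone, median 0.29, camera adjusted p = 0.0563, and adjusted p = 0.176 with an estimated correlation), including Phlda3 (2.46) and Atf3 (2.56). The circadian clock list had 3 of 15 genes lower in liver at 6 weeks (median -0.77, camera adjusted p = 0.00802, and adjusted p = 0.225 with an estimated correlation), and 5 higher and 5 lower at 18 weeks (7 and 5 adjusted over the list alone, camera adjusted p = 0.411, and adjusted p = 0.711 with an estimated correlation).

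The erythroid list had 6 of 8 genes higher in liver at 6 weeks (also adjusted over the list alone, median 2.87, camera adjusted p = 0.00362, and adjusted p = 0.244 with an estimated correlation), with Alas2 at 1.57. The cholangiocyte and ductular list had 3 of 12 higher and 2 lower there (3 and 3 adjusted over the list alone, median -0.26, camera adjusted p = 0.866, and adjusted p = 0.943 with an estimated correlation), with Spp1 at 3.34. The fetal and postnatal liver list had 4 of 10 higher and 1 lower (5 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.17, and adjusted p = 0.36 with an estimated correlation), with the imprinted transcript H19 at 6.63. The adipocyte list was higher in kidney at 4 weeks (0 of 10 called either way, median 1.78, camera adjusted p = 0.00126, and adjusted p = 0.375 with an estimated correlation), a call that ended without the NIF library numbered 1 (adjusted p = 0.115). The podocyte and glomerulus list had 1 of 16 higher in kidney at 8 weeks (also adjusted over the list alone, median 0.14, camera adjusted p = 0.698, and adjusted p = 0.946 with an estimated correlation). The exocrine pancreas list had too few tested genes for a test, with 2 in liver and 1 in kidney.

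The NIF liver library numbered 2 at 3 weeks held 35 counts of Igkc, where the other NIF libraries of that age held 0 and 0 and the controls 30, 41 and 35, so its genotype label is open to question. The NIF liver library numbered 3 at 3 weeks held 13.5 CPM of Retnla, where the other NIF libraries of that age held 0 and 0.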
